A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

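RNA was measured in 4 cultures of budding yeast at 0 h, 2 of a wild-type strain and 2 of a strain carrying histone H3 with lysines 4, 36 and 79 replaced by arginine. Per the labels' protocols, the cultures grew in selective galactose medium to mid-log phase, were harvested at an OD600 of 0.5 to 0.7, and about 20 ug of total RNA per culture was made into biotin-labelled cRNA for an Affymetrix array. Groups and replicate numbers were taken from the sample titles. The design text speaks of replicate cultures, so the arrays of a group were treated as separate cultures. It also names time points of 6 and 9 h, which were not analysed here.

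The deposited values are intensities, 1 signal per probe set on a linear scale, computed by the authors with MAS5 per the submitters' processing notes. The MAS5 version, the scaling target and any later step are not given in the sources used here. On both wild-type arrays the values were multiples of 0.1, and the mean after trimming 2% at each end was 125 and 125. On the mutant arrays every value, 100% within a tolerance of 0.01 steps, was a multiple of a smaller step, 0.0839 on replicate 1 and 0.0960 on replicate 2, and the trimmed means were 105 and 120. A factor of 0.839 and 0.960 per mutant array, or -0.25 and -0.06 on the log2 scale, accounts for this step, and in 0.1 steps all 4 trimmed means were 125. One factor per array does not alter the ranking of probe sets within it, and centring each array removes it up to the added pseudocount. Without centring, the mutant arrays lay at a median of -0.11 (log2) relative to the wild-type arrays. The number of arrays, 2 per group, limits the precision of every comparison.

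The table held 9335 probe sets. The platform annotation paired 6504 of them with 1 gene, 328 with several genes and listed no gene for 2443, and 60 were control probe sets. The 5656 genes behind single-gene probe sets all matched the RefSeq gene table of assembly R64 by gene ID, and 0 symbols changed in this update. That table was used for names and for gene order along chromosomes only, and no coordinates are printed, because the build behind the array annotation is not given in the sources used here. No gene was named from a probe set shared by several genes, and such probe sets are reported as shared. Several fixed genes, among them both histone H3 genes, are present on shared probe sets only.

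A pseudocount of 2, the 10th percentile of all deposited signals, was added before taking log2. Fold changes are therefore on the log2(signal + 2) scale, which understates the change of genes near the background. Probe sets in the lowest 25% of mean signal over the 4 arrays were left out, which set the lowest mean signal among the tested genes at 25.0. For the 269 tested genes with several probe sets, the one of highest mean signal was used. Each array was then centred on its median over the 4576 remaining genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual and 5.63 prior degrees of freedom). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are mutant minus wild type throughout, and a group's SD and each SE refer to 2 arrays per group. Shared, unnamed and control probe sets were fitted apart with the same centring and model, 2123 of them after their own lowest 25% had been left out. They are dimmer as a class: their lowest mean signal was 2.63, and 1344 of them lay under the 25.0 of the tested genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 read the table, and matplotlib 3.10.9 drew the figures.

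The test, 41 gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule took 12 genes per direction, only among those with both mutant arrays beyond both wild-type arrays. Genes past the threshold came first, filled up by smallest unadjusted p. It added the 2 highest and 2 lowest genes of each shifted list, and always the histone H3 and H4 genes, GAL1, GAL7, GAL10, strain markers and mating-type genes. The 38 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were the alternatives. With an estimated correlation camera has only the 2 residual degrees of freedom, so it could call almost no list here. The planned test of genes within a set distance of chromosome ends needs positions. It was replaced by the 10 outermost protein-coding genes of each chromosome end and, beyond these, the next up to 20, a choice made after the annotation had been seen. The distances themselves were not run.

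Alternatives covered the normalisation (none, quantile, cyclic loess), the pseudocount (none or 9, the 25th percentile), the filter (none, or the lowest 50% left out), the mean of all probe sets of a gene, a variance model without trend, a replicate block, each array left out in turn, and other thresholds. The procedure was tested on simulated data with 4576 genes, 200 of them changed, in 10 simulations of this comparison. It recovered 58.0% of genes changed by 1 on the log2 scale, 97.6% at 2, 99.8% at 3 and 100% at 5, and 4.31% of its calls were unchanged genes. With 200 genes changed the adjusted threshold is easier to reach than with few. The recovery rates may therefore overstate what this comparison, with 2 genes past the threshold, could find. Camera called 0% of unshifted lists, and called a list shifted by 0.5 in 100% of simulations. The simulated genes varied independently, whereas the estimated correlation was 0.36 in the stress list and 0.71 in the cytosolic ribosomal proteins. The 0% therefore does not cover lists whose genes vary together.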

Results

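Transcript levels were compared between 2 wild-type and 2 H3 K4,36,79R cultures of Saccharomyces cerevisiae at 0 h. Lysines 4, 36 and 79 of histone H3 are the residues methylated by Set1, Set2 and Dot1, and arginine at these positions cannot be methylated by them. In the time course this series belongs to, cells growing in galactose are moved to glucose, which shuts off the wild-type H3 gene so that mutant H3 alone is made. The 0 h samples precede that move, and the comparison asks which transcripts already differed between the strains in galactose. Signals were read on 9335 probe sets per array, and 4576 genes were tested. Median deposited signals were 47.6 and 39.3 on the wild-type arrays and 38.6 and 42.9 on the mutant arrays. Replicates correlated at a Spearman coefficient of 0.951 in the wild type and 0.978 in the mutant, across genes, which are not independent replicates. The SD of log2 differences between replicates was 0.43 in the wild type and 0.27 in the mutant, and 104 and 26 genes lay at least 2-fold apart between replicates.

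The strains differed most in URA3 (YEL021W), which encodes orotidine-5'-phosphate decarboxylase of uracil synthesis and is a common selection marker. Its deposited signal was 14.1 and 14.6 in the wild-type cultures and 594 and 643 in the mutant cultures. On the log2 scale, URA3 stood at 3.98 ± 0.08 in the wild type and 9.33 ± 0.01 in the mutant (SD, n = 2 each), a rise of 5.35 (SE 0.17, 40.8-fold, limma adjusted p = 9.73e-06). Both wild-type signals of URA3 lay under the lowest mean signal among the tested genes, near background. The rise and its fold are therefore read as lower bounds, a limit that the SE does not cover. SIP18 (YMR175W), a gene of the osmotic and desiccation stress response, rose by 1.64 (SE 0.16, 3.12-fold, adjusted p = 0.0202), from deposited signals of 83.1 and 83.8 to 246 and 245. These 2 genes were the only ones past the threshold in limma, and 0 genes fell past it. At an unadjusted p under 0.05 there were 390 genes, 225 higher and 165 lower. By chance alone a fraction of 0.05 of the 4576 tested genes is expected at that level. URA3 stayed past the threshold without any one array, whereas SIP18 had an adjusted p of 0.0759 without wild-type replicate 1 and 0.194 without wild-type replicate 2, at differences of 1.60 and 1.68 in fits with 1 residual degree of freedom. Its adjusted p was 0.0766 with a variance model that has no intensity trend.

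The number of genes past the threshold depended on the scaling. Without centring it was 11 (6 higher, 5 lower), with quantile normalisation 9 (5 higher, 4 lower) and with cyclic loess 8 (5 higher, 3 lower), against 2 higher and 0 lower with median centring. It was 1 without wild-type replicate 1, 1 without wild-type replicate 2, 14 without mutant replicate 1 and 21 without mutant replicate 2. Those counts without an array come from fits with 1 residual degree of freedom, in which a lone array is taken to vary like the other group. They are therefore not comparable with the count on all arrays. At an adjusted p under 0.10 on all arrays, 17 genes were found, 12 higher and 5 lower. Both mutant arrays lay beyond both wild-type arrays for 39.4% of genes, where chance gives 33.3%, and 31 of these genes differed at least 2-fold (20 higher, 11 lower). The 2 other ways of splitting the arrays into pairs gave 0 genes each past the threshold, with 125 and 80 at an unadjusted p under 0.05. Each of these splits mixes the strains within a group, so strain differences add to the spread there. Their counts are therefore no chance baseline for the comparison of strains.

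**Figure D1:**
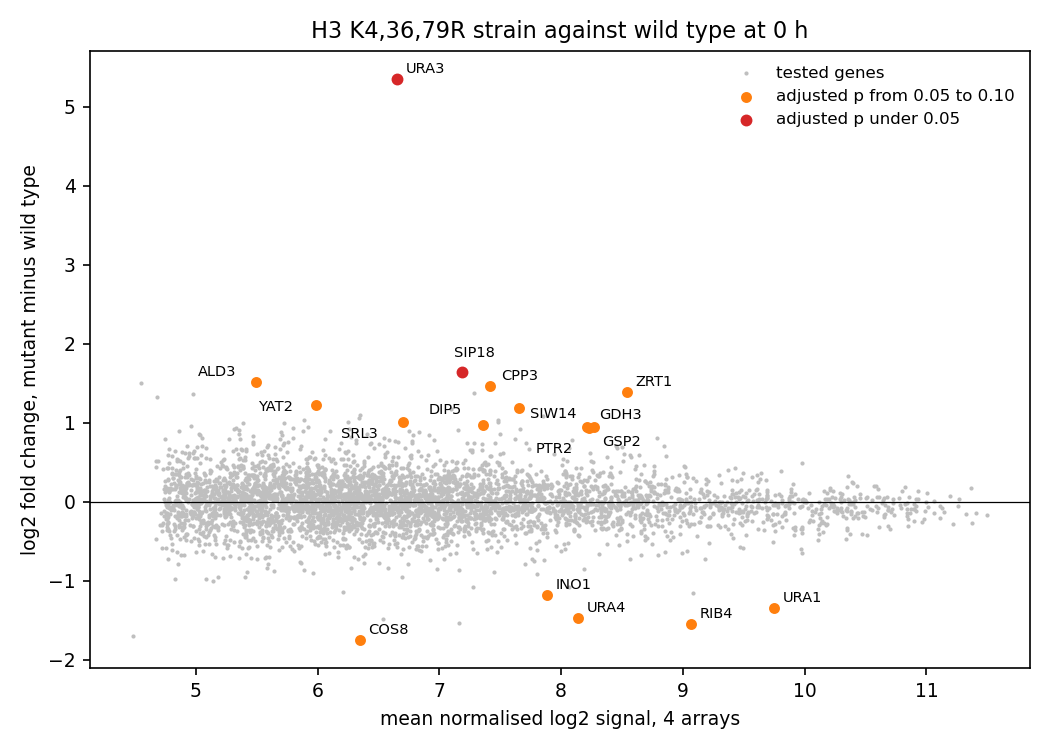
Log2 fold change of each of 4576 tested genes (mutant minus wild type, vertical axis) against its mean normalised log2 signal over 4 arrays (horizontal axis), grey for all genes, orange for an adjusted p from 0.05 to 0.10 and red for one under 0.05. URA3 stands apart at 5.35, SIP18 follows at 1.64, and URA1, URA4, RIB4, INO1 and COS8 are the coloured points below 0.

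The 10 further genes named on the higher side did not pass the threshold, with adjusted p-values from 0.0552 to 0.0992. Of 10 alternative settings, ZRT1 and CPP3 passed in 6, ALD3 in 5, and the rest in at most 2. The zinc transporter gene ZRT1 differed by 1.39 (SE 0.18) and the aldehyde dehydrogenase gene ALD3 by 1.51 (SE 0.20), both at an adjusted p of 0.0552. ZRT1 has 4 probe sets, of which 3 gave log2 differences from 1.39 to 1.68 and the dimmest gave -0.28. CPP3 differed by 1.46, the phosphatase gene SIW14 by 1.19 and the carnitine acetyltransferase gene YAT2 by 1.23. Smaller differences were measured for the dicarboxylic amino acid permease gene DIP5 (0.98), the Ran homologue gene GSP2 (0.95), the glutamate dehydrogenase gene GDH3 (0.95), SRL3 (1.01) and the peptide transporter gene PTR2 (0.93).

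The 12 genes named on the lower side did not pass the threshold, with adjusted p-values from 0.0552 to 0.178. Of 10 alternative settings, URA4 and RIB4 passed in 6, URA1 in 5, INO1 and COS8 in 3, and the rest in at most 2. URA4 (dihydroorotase) and URA1 (dihydroorotate dehydrogenase), which precede URA3 in uracil synthesis, differed by -1.47 (SE 0.17, adjusted p = 0.0552) and -1.34 (SE 0.20, adjusted p = 0.0787). Deposited URA4 signals were 453 and 520 in the wild type against 141 and 184 in the mutant. RIB4, the lumazine synthase gene of riboflavin synthesis, differed by -1.55 (SE 0.21) and INO1, the inositol-3-phosphate synthase gene, by -1.18 (SE 0.15), both at an adjusted p of 0.0552. COS8, COS7 and COS4 of a subtelomeric membrane protein family differed by -1.75, -1.48 and -1.08, measured on probe sets whose design marks sequence shared with relatives. The kynureninase gene BNA5 (-1.14), the cytosolic malate dehydrogenase gene MDH2 (-1.16), the adenine deaminase gene AAH1 (-0.95), the mating-type endonuclease gene HO (-0.89) and STP4 (-0.85) completed the group.

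**Figure D2:**
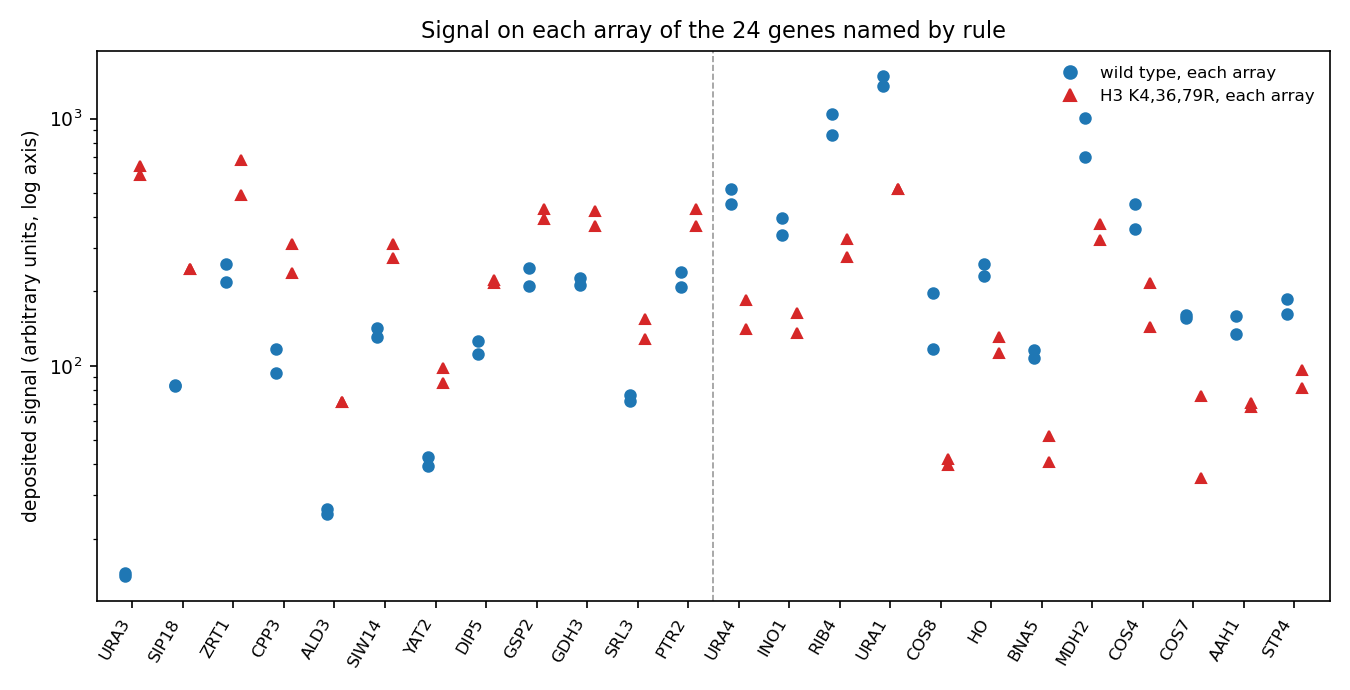
Deposited signal (arbitrary units, log axis) of the 24 genes named by rule, 1 point per array, blue circles for the 2 wild-type and red triangles for the 2 mutant cultures; the dashed line parts genes higher from genes lower in the mutant. The rule took only genes whose arrays do not overlap between the strains, and URA3 has the widest gap, from 14.6 to 594.

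Probe sets of the core histone genes did not pass the test at 0 h. HHT1 and HHT2, which encode H3, were read only on 3 probe sets shared between them. Of these, 2 showed log2 differences of -0.07 (SE 0.32) and 0.38 (SE 0.27), neither past the test, and the third lay below the filter with signals from 1.73 to 3.6. Such probe sets do not tell a mutant copy from a wild-type copy, so they do not check the genotype. The shared H4 probe set of HHF1 and HHF2 showed 0.16 (SE 0.30), those of HTA1 and HTA2 showed -0.10 and -0.06, and HTB1 and HTB2 differed by -0.34 and -0.43. Of the galactose list, 0 of 10 measured genes passed the test over all genes, 0 adjusted over the list alone, and 9 were lower, with a median of -0.15. GAL1, GAL7 and GAL10, the structural genes of galactose use, differed by -0.21 (SE 0.22), -0.33 (SE 0.24) and -0.37 (SE 0.20). GAL7 was at -0.51 without wild-type replicate 1, -0.14 without wild-type replicate 2 and -0.22 without mutant replicate 1, and GAL10 at -0.22 without mutant replicate 1. Camera did not call this list (adjusted p = 0.200), whereas fry, which asks whether a list's own genes move one way, gave an adjusted p of 0.000522.

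Strain markers other than URA3 did not pass the test. LEU2 (0.06), HIS3 (-0.01), ADE2 (-0.06), MET17 (0.09), CAN1 (-0.20), HIS4 (-0.37), ADE1 (-0.58) and LYS2 (-0.59) were all measured, and TRP1 lay below the filter with signals from 0.5 to 3.17. Without centring LEU2 and MET17 took the opposite sign, and with quantile normalisation or cyclic loess ADE2 did. Without wild-type replicate 1 HIS4 was at -0.70, ADE1 at -0.93 and CAN1 at -0.33, and without wild-type replicate 2 at -0.042, -0.24 and -0.072. Without one array or another LEU2, HIS3, ADE2 and MET17 took either sign. Over the 9 measured markers the median was -0.06 and the mean, carried by URA3, 0.41, and camera gave an adjusted p of 0.979, or 0.0201 (upward) without mutant replicate 1. Adjusted over the list alone, 1 gene rose. Genes specific to mating type a were read in both strains, with deposited signals of MFA2 from 534 to 921 and of MFA1 from 344 to 420. Their log2 differences, for MFA1 (-0.13), MFA2 (-0.32), STE2 (-0.01), STE6 (0.28), BAR1 (-0.52) and AGA2 (0.15), did not pass the test, and the list had an adjusted p of 0.620. MFA1 was read on a probe set whose design marks shared sequence, and the mean of its 2 probe sets gave -0.37. Without an array, MFA1 ranged from -0.21 to -0.037, BAR1 from -0.78 to -0.25 and AGA2 from 0.038 to 0.26, and MFA2, STE2 and STE6 took either sign. ASG7 lay below the filter. Of the alpha-specific genes, SAG1 (0.34; 0.22 without mutant replicate 1) and AFB1 (0.13; -0.13 without wild-type replicate 1 and 0.39 without wild-type replicate 2) were tested without a call. MF(ALPHA)1 (16.1 to 19.8), MF(ALPHA)2 (5.9 to 8.8) and STE3 (4.95 to 8.1) lay below the filter in all 4 cultures.

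Of 38 gene lists tested, camera called 6. The general stress response list shifted up by a median of 0.25 over 55 measured genes, of which 38 were higher and 17 lower (adjusted p = 1.83e-06; 0.907 with an estimated correlation). One of its genes, SIP18, rose over all genes tested and 9 rose when adjusted over the list alone, while 54 did not pass the test over all genes. ALD3 differed by 1.51, and the lowest members were TMA10 (-0.52) and GPP2 (-0.43), the latter a glycerol-3-phosphate phosphatase gene; TMA10 was at -0.28 without mutant replicate 2, and GPP2 at -0.67 without wild-type replicate 1 and -0.20 without wild-type replicate 2. The shift was 0.05 (adjusted p = 0.400) without wild-type replicate 1 and 0.38 without wild-type replicate 2. The wild-type replicates themselves differed by a median of 0.32 on this list and the mutant replicates by 0.09.

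Genes of NAD and thiamine synthesis shifted down, by a median of -0.38 over 15 measured genes, 13 of them lower (adjusted p = 0.000437; 0.907 with an estimated correlation). Over all genes tested 0 passed the test, and 3 fell when adjusted over the list alone. The lowest were BNA5 (-1.14) and BNA6 (-0.91) of NAD synthesis from tryptophan, and the highest BNA3 (0.49) and BNA4 (0.25). BNA3 and BNA4 were at 0.97 and 0.37 without wild-type replicate 1 and at 0.0098 and 0.12 without wild-type replicate 2. Camera with the preset correlation called this list in 10 of 10 alternative settings and in 4 of 4 fits without an array, with medians from -0.60 without wild-type replicate 1 to -0.29 without wild-type replicate 2.

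The 3 ribosome-related lists shifted down by smaller amounts, with 0 genes past the test over all genes and 0 adjusted over each list alone. In ribosome biogenesis 72 of 99 genes were lower (median -0.12, adjusted p = 0.00101; 0.907 with an estimated correlation), with ENP1 at -0.72 and FAF1 at -0.68 and, at the other end, MAK21 and UTP20 at 0.24 each. FAF1 was at -0.38 without mutant replicate 1, and MAK21 and UTP20 were at 0.64 and 0.72 without wild-type replicate 1 and at -0.15 and -0.24 without wild-type replicate 2. The call ended without wild-type replicate 1 (median -0.11, adjusted p = 0.243) and without mutant replicate 2 (median -0.06, adjusted p = 0.163). In mitochondrial ribosomal proteins 55 of 66 genes were lower (median -0.11, adjusted p = 0.00123; 0.907 with an estimated correlation), among them RSM25 (-0.70) and MRPL27 (-0.65), with MRPL3 (0.40) and RSM22 (0.30) highest; without wild-type replicate 1 these 2 were at 0.78 and 0.63, and without wild-type replicate 2 at 0.021 and -0.030. That call ended without wild-type replicate 1 (median -0.16, adjusted p = 0.0745) and without mutant replicate 2 (median -0.09, adjusted p = 0.0996). In cytosolic ribosomal proteins 68 of 81 genes were lower (median -0.14, adjusted p = 0.0116; 0.921 with an estimated correlation), from RPL7B (-1.53) and RPL38 (-0.49) to RPP2B (0.18) and RPS14B (0.33). This list was not called with quantile normalisation or cyclic loess, nor without mutant replicate 1 (median -0.12, adjusted p = 0.0959) or mutant replicate 2 (median -0.14, adjusted p = 0.118). Its direction turned without wild-type replicate 2 (median 0.08, adjusted p = 0.00641), its median was -0.40 without wild-type replicate 1, and the wild-type replicates differed by 0.46 on it. RPL38 was at -0.30 without wild-type replicate 2, and RPP2B at 0.025 without wild-type replicate 1, 0.34 without wild-type replicate 2 and 0.077 without centring. RPL7B was read at 103 and 603 in the wild-type replicates, on a probe set whose design marks shared sequence. Its second probe set, marked likewise, gave -0.09, and the mean of both -0.81. RPL7B was at -2.83 without wild-type replicate 1 and -0.23 without wild-type replicate 2. It was at -1.31 without mutant replicate 1 and -1.74 without mutant replicate 2. In those fits the wild-type replicates, far apart for this gene, gave its only spread within a group, so no call is drawn from them. Summed deposited signal of 10 control probe sets for ribosomal RNA was 1280 and 1343 in the wild type and 585 and 413 in the mutant. These sums were neither centred nor tested. A difference in sample preparation between the groups cannot be told apart from one in the cells. The ratio of 3' to 5' control probe sets was 1.53 and 1.40 in the wild type and 1.81 and 1.53 in the mutant for actin. It was 3.36 and 2.72 against 3.55 and 2.38 for SPT15, and 3.59 and 6.82 against 5.25 and 3.96 for SRB4.

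The cell wall list shifted up by a median of 0.12 (21 of 31 genes higher, adjusted p = 0.0476; 0.907 with an estimated correlation), with 0 genes past the test over all genes and 0 adjusted over the list alone. PIR3 (0.70) and YPS1 (0.55) were highest and GAS3 (-0.30) and GSC2 (-0.21) lowest. GSC2 was at -0.43 without wild-type replicate 1, -0.0025 without wild-type replicate 2 and -0.14 without mutant replicate 1, and at 0.078 with the mean of probe sets. GAS3 was at -0.17 without wild-type replicate 2, -0.51 without mutant replicate 1 and -0.10 without mutant replicate 2. Among the fits without an array it kept its call only without wild-type replicate 2 (median 0.22), with a median of 0.05 and an adjusted p of 0.891 without wild-type replicate 1, and medians of 0.14 (adjusted p = 0.107) without mutant replicate 1 and 0.11 (adjusted p = 0.163) without mutant replicate 2. It was also not called without centring, with the larger pseudocount or without a filter. With an estimated correlation 0 of the 38 lists were called, and fry called 1, the galactose list. Fry called none of the lists that camera called, with adjusted p-values from 0.337 for mitochondrial to 0.754 for cytosolic ribosomal proteins. Camera with an estimated correlation has 2 degrees of freedom, so its result does not tell whether correlation between genes undoes a call. For NAD and thiamine synthesis the estimated correlation was 0.0080, under the preset 0.01, and camera's adjusted p was still 0.907. For the stress and cytosolic ribosomal protein lists the estimate was 0.36 and 0.71, far above the preset. Camera's p-values with the preset are therefore too small for these lists, and fry gave unadjusted p-values of 0.205 and 0.595. The number of lists called was 4 without wild-type replicate 1, 10 without wild-type replicate 2, 5 without mutant replicate 1 and 2 without mutant replicate 2. Camera also called 5 and 3 lists in the 2 other splits of the arrays into pairs.

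**Figure D3:**
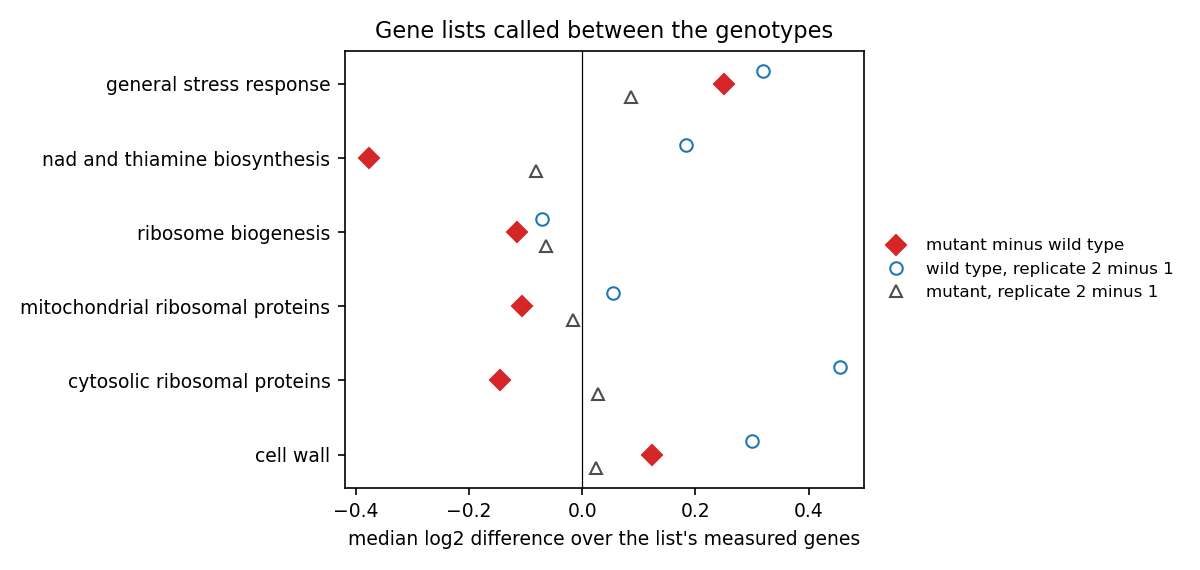
Median log2 difference over the measured genes of the 6 lists camera called, as red diamonds for mutant minus wild type, open circles for replicate 2 minus replicate 1 of the wild type and open triangles for the same in the mutant. For the stress, cell wall and cytosolic ribosomal protein lists the wild-type replicates lay further apart (0.32, 0.30 and 0.46) than the strains did. Replicate differences are between single arrays and strain differences between means of 2 arrays, so the former vary more.

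Measured genes that act on the replaced lysines and on silencing were not called; SET2, with signals from 3 to 14.9, and the silencing genes SIR1 and SIR4 lay below the filter. The list of H3 lysine methylation machinery had 14 genes higher and 16 lower of 30 measured among 39 listed (median -0.02, mean 0.0036, adjusted p = 0.979), with the methyltransferase genes SET1 at 0.28 (SE 0.19) and DOT1 at -0.46 (SE 0.25). The silencing factors had 9 of 12 measured genes higher, of 19 listed (median 0.07, adjusted p = 0.261), with SAS4, of a histone acetyltransferase complex, highest at 0.92 (SE 0.23, adjusted p = 0.318), SIR3 at 0.46 and SIR2 at 0.04. In both lists 0 genes passed the test over all genes and 0 adjusted over the list alone. SET1, SET2, DOT1 and the SIR genes were named for their function, and SAS4 for its value, after their values had been seen. The 10 outermost genes of each chromosome end, 117 measured, had a mean log2 difference of -0.06 and a median of -0.02 (54 higher, 63 lower, adjusted p = 0.454; 0.907 with an estimated correlation). Over all genes tested 0 of them passed the test; adjusted over the list alone, 6 rose and 6 fell. The next genes inward, 227 measured, had a median of -0.01 and an adjusted p of 0.979. For the 5 outermost genes, 35 measured, a setting chosen after the data were seen, the mean was -0.23 (adjusted p = 0.00968), and -0.14 (adjusted p = 0.131) without COS genes. A list of subtelomeric gene families, 11 measured genes including the COS genes, had a median of 0.25 and a mean of -0.13 (adjusted p = 0.979). With the lowest 50% of probe sets left out, 5 of its genes were measured and camera called it downward (4 of 5 lower, mean -0.68, adjusted p = 0.0319).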

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

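The control-probe test for URA3, the tests of COS probe sets and chromosome ends, the tests without wild-type replicate 1 and the use of cytosolic ribosomal proteins in weighing variation between cultures were chosen only after the result was seen; the other tests below were written after the patterns had been noticed but before their own values were seen. A signal outside the genes tested drew attention: a control probe set for URA3, left out of the comparison with the other control probe sets, read 21.6 and 18.2 in the wild type and 976 and 916 in the mutant. Its log2 difference was 5.55 (SE 0.30, limma adjusted p = 0.000604 among 2123 probe sets fitted apart). Both of its wild-type signals lay under the lowest mean signal among the tested genes, near background, so 5.55 is read as a lower bound.

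The first pattern weighed is URA3 high with URA1 and URA4 low in the mutant cultures. A fault of the tested URA3 probe set is argued against by the control probe set, at 5.55. A marker difference that lowers the whole pathway is argued against too, since the other 6 measured genes of pyrimidine synthesis had a median of 0.058. A marker difference that reaches only URA1 and URA4, genes known to be activated by Ppr1 along with URA3, may account for the pattern, but no strain markers are given in the sources used here and no test separates it from an effect of mutant H3.

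The second pattern is stress genes higher with ribosome biogenesis genes lower in the mutant. Wild-type replicate 2 alone does not set it, since the stress median was 0.38 without that array. Without wild-type replicate 1 it was 0.053, so that array may carry most of the stress part; ribosome biogenesis stood at -0.107 without it (adjusted p = 0.243), against -0.116 on all arrays, and whether that part rests on it stays open. Variation between cultures along a growth or stress axis stays open: the wild-type replicates differed by 0.32 on the stress list and -0.07 on ribosome biogenesis, against 0.25 and -0.12 between the strains, but by 0.46 on the cytosolic ribosomal proteins, which such an axis would lower along with ribosome biogenesis and which stood at -0.14 between the strains. Replicate differences are between single arrays and strain differences between means of 2 arrays, so the former vary more and the sizes are not on equal terms. An effect of mutant H3 stays open and untested.

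The third pattern is COS4, COS7 and COS8 lower in the mutant, beside COS6 at -0.17 and COS9 at -0.26, or -1.06 on a COS9 probe set marked for shared sequence. For COS8, the probe set without a shared-sequence mark showed -1.43, which argues against cross-hybridisation only if it reads COS8 alone. The missing mark does not settle that, as some unmarked probe sets of this array are annotated to several genes. For COS4 and COS7 cross-hybridisation cannot be told apart from a change in these genes, as 0 unmarked probe sets exist for them. A shift shared by all of the 10 outermost genes of each end is argued against, since the other 112 measured had a median of -0.0080 (SD 0.43) against -1.08 for the 5 COS genes. A shift limited to the very ends stays open: the 5 outermost genes had a mean of -0.23 (adjusted p = 0.00968; -0.14 and 0.131 without COS genes), and the 24 shared Y' helicase probe sets, outside that test and 12 of them near background, had a median of -0.78. A change in COS genes in the mutant, or in their copy number, was not tested.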

How the results depend on the processing

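The settings of 5 and 15 outermost genes and those without COS genes were chosen after the data were seen. The planned distances from chromosome ends were not run. URA3 was called in 10 of 10 settings and 4 of 4 fits without an array, SIP18 in 9 of 10 and 2 of 4. Of all named genes' values under the alternatives, 791 kept direction and side of the threshold, 73 newly passed it, 3 lost it and 22 turned direction; of list shifts 67 kept both, 28 lost the call and 1 turned. The count of 2 genes became 11 without centring, 9 with quantile normalisation, 8 with cyclic loess, 7 with the lowest 50% left out, 9 with the mean of probe sets, 1 without the intensity trend, 17 at an adjusted p under 0.10 and 390 at an unadjusted p under 0.05. Without an array it ranged from 1 to 21 and the count of 6 lists from 2 to 10, in fits with 1 residual degree of freedom that take a lone array to vary like the other group. The list count was 0 with an estimated correlation, a test with 2 degrees of freedom that could call almost no list. It was 1 with fry, the galactose list, which is not among the 6. Lists called only in alternatives included protein folding, upward with quantile normalisation (adjusted p = 0.00942) and cyclic loess (0.0465), and glycolysis, downward without wild-type replicate 1 (0.000583) and upward without wild-type replicate 2 (0.0435). With the replicate number as a block, 32 genes and 5 lists, without the cell wall list, were called. Replicate differences correlated at 0.04 across 4576 genes, which gives no sign of pairing; whether a number marks a shared day is not given in the sources used here. The outermost-gene mean of -0.06 was -0.23 (adjusted p = 0.00968) for 5 genes per end and -0.04 for 15; its adjusted p ranged from 0.00968 to 0.907. Genes not called turned direction as follows. Without centring, LEU2 was -0.0504 and MET17 -0.012; ADE2 was 0.027 with quantile normalisation and 0.0079 with cyclic loess; with the mean of probe sets GSC2 was 0.078, LEU2 -0.41 and HIS3 0.17. Without an array, values ranged from -0.032 to 0.14 for LEU2, -0.070 to 0.26 for MET17, -0.24 to 0.22 for STE2, -0.13 to 0.39 for AFB1, -0.15 to 0.64 for MAK21, -0.24 to 0.72 for UTP20, -0.030 to 0.63 for RSM22, -0.35 to 0.33 for HIS3, -0.69 to 0.051 for MFA2, -0.28 to 0.85 for STE6 and -0.17 to 0.055 for ADE2, and from -0.40 to 0.078 for the cytosolic ribosomal protein list. The cause was not tested. Signals near background limit low genes, which the pseudocount draws together.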

Other observations

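Groups in this part were chosen after the data were seen, and their values are descriptions. Genes already named above are among their members, so an adjustment over a group alone is no independent test. Genes listed for the kynurenine pathway of tryptophan lay lower in the mutant in 5 of 7 cases, with a median of -0.60. BNA1 (-0.60), BNA5 (-1.14), BNA6 (-0.91) and BNA7 (-0.89) passed an adjustment over these 7 genes alone, but none of them passed over all genes tested, and BNA2 (-0.27), BNA3 (0.49) and BNA4 (0.25) did not pass either. In riboflavin synthesis RIB4 (-1.55) stood apart from RIB1 (-0.24), RIB2 (-0.00053), RIB3 (0.06), RIB5 (0.21) and RIB7 (-0.39). The uridine permease gene FUI1 was at -0.74 (adjusted p = 0.239), whereas the uracil permease gene FUR4 was at 0.22.

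Genes of carnitine and acetyl-unit handling lay higher in the mutant in 7 of 8 cases, with a median of 0.51. They included the peroxisomal citrate synthase gene CIT2 (1.37, SE 0.26), YAT2 (1.23), ATO2 (0.71) and CRC1 (0.60), with the acetyl-CoA synthetase gene ACS1 at -0.27. Adjusted over these 8 genes alone 3 were higher, and over all genes tested 0 passed. Of 14 genes for amino acid and peptide uptake, 9 were higher, with a median of 0.11, and DIP5 and PTR2 passed an adjustment over the group alone.

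Repeated families at chromosome ends were read on probe sets shared by several genes, which did not enter the comparison of named genes. All 7 shared COS probe sets were lower in the mutant, with a median of -0.85 and a range from -0.94 to -0.79. All 24 probe sets shared by the helicase genes of the Y' elements (YRF1 family) were lower, with a median of -0.78 and a range from -1.42 to -0.10. Of these, 12 had a mean signal under that of any tested gene, near background, among them 5 of the 11 at an unadjusted p under 0.05. The 12 brighter ones also had a median of -0.78, with a range from -0.99 to -0.26. Camera gave adjusted p-values of 3.83e-08 and 1.93e-15 for these sets with the preset correlation. With an estimated correlation, a test with 2 degrees of freedom, they were 0.0985 and 0.133. Probe sets of a family read much the same transcripts, and 0 of these probe sets passed limma's test alone, against 6 COS and 11 Y' probe sets at an unadjusted p under 0.05. The wild-type replicates differed by a median of -0.31 and the mutant replicates by 0.46 on the Y' set, and by -0.15 and 0.13 on the COS set.

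Bacterial control transcripts gave no single scale between the arrays as deposited. Relative to wild-type replicate 1, the 15 probe sets of dap, lys, phe, thr and trp stood at a mean log2 of -0.16 in wild-type replicate 2, -0.02 in mutant replicate 1 and -0.15 in mutant replicate 2. The 9 of lys, phe and thr alone stood at 0.17, 0.02 and 0.05, and the 9 of bioB, bioC, bioD and cre at 0.34, -0.01 and 0.11.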
